A study of Mus musculus with 67 samples.

How the data were processed

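RNA was sequenced from 67 libraries of mouse monocytes and marrow progenitors, sorted by flow cytometry after CD115 enrichment in the submitters' notes, with RNA captured on oligo-dT beads. The notes name bcl2fastq, HISAT 0.1.5, SAMtools and HOMER with the genome build mm9, and state neither the counting options nor the annotation. Each of the 3 deposited tables gives 24421 genes by symbol and a RefSeq transcript. All 67 libraries were matched to columns by their labels, 28 groups were formed from population, tissue, genotype, time and host or graft, and 0 columns were left over. No genome coordinates were used, because the reference at hand is a later build than mm9. It served for names, chromosomes and gene order only, and 10871 of the 11388 genes tested in the knockout table were found in it.

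In the 7-week and knockout tables the authors deposited signal values, gene counts scaled to a library-wide total that includes reads outside the listed genes. Over these genes the columns sum to 5981863 to 7335815 and to 7399419 to 8147897. The total is taken to be 10000000, the usual HOMER output, which the labels do not state, so RPM values in these tables carry that assumption. Plain ratios of RPM within a table do not. Fitted log2 ratios do, through the 1 RPM added before the log and the filter at 2 RPM, which matter most for low genes. Every column holds whole multiples of its own step, so reads were recovered by division, all of them whole within 0.1 read. In blood Ly6Cint replicate 2 of the 7-week table the step is close to a power of 10, so this check says nothing there. For the transfer table the authors deposited score values, scaled to a common total per library of 2281423 to 2282712 and rounded, from which neither reads nor depth can be recovered, and these were divided to a total of 1000000. Where a gene is 0 in a whole group of that table its values are given and no ratio. A few symbols share sequence with a neighbour or a retained copy (Apoc2, Rpl26, Hba-a1, Hbb-b1, the Bcl2a1 family, Ly6c1 and Ly6c2), and how their reads were divided is not stated.

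The test planned for counts, the edgeR quasi-likelihood test with TMM, was replaced by the one planned for normalized values. That was limma trend (limma 3.58.1, R 4.3.3) on log2 of RPM plus 1, with all libraries of a table in 1 fit, 1 mean per group, no block, and Benjamini-Hochberg adjusted p under 0.05 as the call. Genes needed 2 RPM in at least 3 libraries (7-week) or 2 (knockout, transfer), leaving 11373, 11388 and 12096 genes. Tables were never mixed in a fit. A fit with 2 libraries per group borrows its spread from the other groups. Samples, comparisons, tests, gene lists and alternatives were fixed before the data were examined. Replicate numbers were not used as pairs, and a block for them was an alternative where the compared groups share at least 2 of them.

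The 21 gene lists were Ly6C+ monocyte (17 genes), Ly6C- monocyte (24), MHC class II and dendritic cell (20), progenitor (20), primary granule (14), cell cycle (39), interferon response (35), NF-kappaB inflammatory (26), immediate early (23), monocyte transcription factor (36), apoptosis regulator (25), adhesion and chemotaxis receptor (28), complement and scavenger (24) and ribosomal protein genes (69), with markers of neutrophils (16), B cells (14), T and NK cells (21), erythroid cells (16), platelets (13), tissue macrophages (15), and plasmacytoid dendritic cells and basophils (13). Each was tested in 20 comparisons with camera at a preset correlation of 0.01, giving 420 tests adjusted together, of which 170 were called. With the correlation estimated from the residuals 84 were called, all of them among the 170. The lists hold well-known genes of each class, some of which monocytes express themselves.

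Genes were named by a rule. Among genes called in a comparison, with every library of the higher group above every library of the lower and a mean of at least 20 RPM in the higher group, the 10 with the largest log2 ratio in each direction qualified (5 in the transfer table), leaving out clone, predicted-gene, microRNA and small nucleolar names. Up to 4 called members of each list, those with the smallest p, qualified too, and so did, whatever their test, Ly6c2, Ccr2, Cx3cr1, Nr4a1, Cebpa, Cebpb, Cebpd, Klf4, Irf8 and Spi1. Not every qualifying gene appears in the text. Ciita in the knockout table and Capg were chosen after their values were seen, as were the genes given for the duplicate marrow libraries, for differences between tissues and for MHC class II across tables.

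The signature took the 100 called genes with the largest rise and the 100 with the largest fall between 7-week blood Ly6C- and Ly6C+ monocytes, with at least 20 RPM in the higher group. A library's score was the mean log2 value of the rising minus that of the falling genes, set to 0 and 100 at the Ly6C+ and Ly6C- means of its table and tissue, those of the hosts for grafts. Correlations with time used an exact permutation test, two-sided. Simulated data held 200 changed genes, all drawn from genes averaging at least 20 RPM over the table, so recovery of lower genes was not measured. The group sizes and library depths were those of a comparison, with 1 common spread estimated over its whole table. Limma recovered 89.6% of changes of 2-fold and 100% of 4-fold for cMoP against MDP, and 67.2% and 100% for blood Ly6C- against Ly6C+. For ko against wt Ly6Cint it recovered 23.9% and 97%. For graft blood at 48 against 24 h the spread and the depth were assumed, not estimated. There 0% of 2-fold, 16.4% of 4-fold and 51.5% of 8-fold changes were recovered, which does not measure the power of the graft data. Intervals are at 95% and cover counting error only, since reads without molecular tags are not independent molecules.

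The alternatives fixed beforehand were quantile normalization, limma without trend, no filter and a filter at 5 RPM, pseudocounts of 0.5 and 5, only the compared groups in the fit, the replicate block and leaving out each replicate. For the signature they were 50 genes, a pseudocount of 5 and a signature from another set of animals, for lists the estimated correlation, and for correlations between tables the genes of at least 20 RPM in every table. Added after seeing the data were scaling to the total of the listed genes, edgeR 4.0.16 with TMM on the recovered reads (not possible for the transfer table), array weights per library, for ko against wt leaving out genes on X and Y, quantile normalization and scaling to the listed genes for differences between tissues, a pairwise filter at 20 RPM for correlations between tables, and for graft spleen against blood a block on time and replicate letter.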

Results

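RNA sequencing was done on sorted mouse monocytes and their bone marrow progenitors, giving 67 libraries in 28 groups held in 3 tables. The 7-week table has 25 libraries of C57BL/6 mice: from bone marrow, the monocyte and dendritic cell progenitor (MDP, n = 4), the common monocyte progenitor (cMoP, n = 4), Ly6C+ monocytes (n = 3) and Ly6C- monocytes (n = 4), and from blood, Ly6C+ (n = 4), Ly6Cint (n = 3) and Ly6C- monocytes (n = 3). Ly6C is the surface antigen by which mouse monocytes are sorted into classical (Ly6C+) and patrolling (Ly6C-) cells, with Ly6Cint between them. The knockout table has 16 libraries: blood Ly6C+, Ly6Cint and Ly6C- monocytes of wt mice and Ly6C+ and Ly6Cint monocytes of ko mice (16 weeks, mixed background, n = 2 each), with marrow MDP, cMoP and Ly6C+ duplicates (8 weeks, n = 2 each). No ko Ly6C- library is held. The transfer table has 26 libraries (8 weeks, n = 2 per group). They are marrow Ly6C+ monocytes before transfer, the transferred cells recovered from blood and spleen after 24, 36 and 48 h, and host monocytes of both tissues. The titles of the host libraries name Gr1 in place of Ly6C, and their P, Int and M sorts are called Ly6C+, Ly6Cint and Ly6C- here.

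The deposited values allow 577690 to 3643327 reads per library on the listed genes to be recovered in the 7-week table (median 1066378) and 942751 to 5478761 in the knockout table (median 1940218.5). The depth of the transfer libraries is unknown. Genes above 0 numbered 10558 to 12917 per library in the 7-week table, 11055 to 12555 in the knockout table and 7734 to 11719 in the transfer table, where the graft libraries of blood at 24 h (8109 to 8278) and 48 h (7734 to 8761) and of spleen at 48 h (8396 to 8614) were lowest. Between replicates of a group Pearson's r across genes was 0.803 to 0.987 over 54 pairs, across genes that are not independent replicates. The labels do not say whether replicates are separate animals, so the p-values may measure technical spread only. Values are reads per 1000000 reads of a library (RPM) unless stated, means carry the SD, log2 ratios carry the SE of limma, and p-values are adjusted over all genes tested or, for gene lists, over all 420 list tests.

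**Figure D1:**
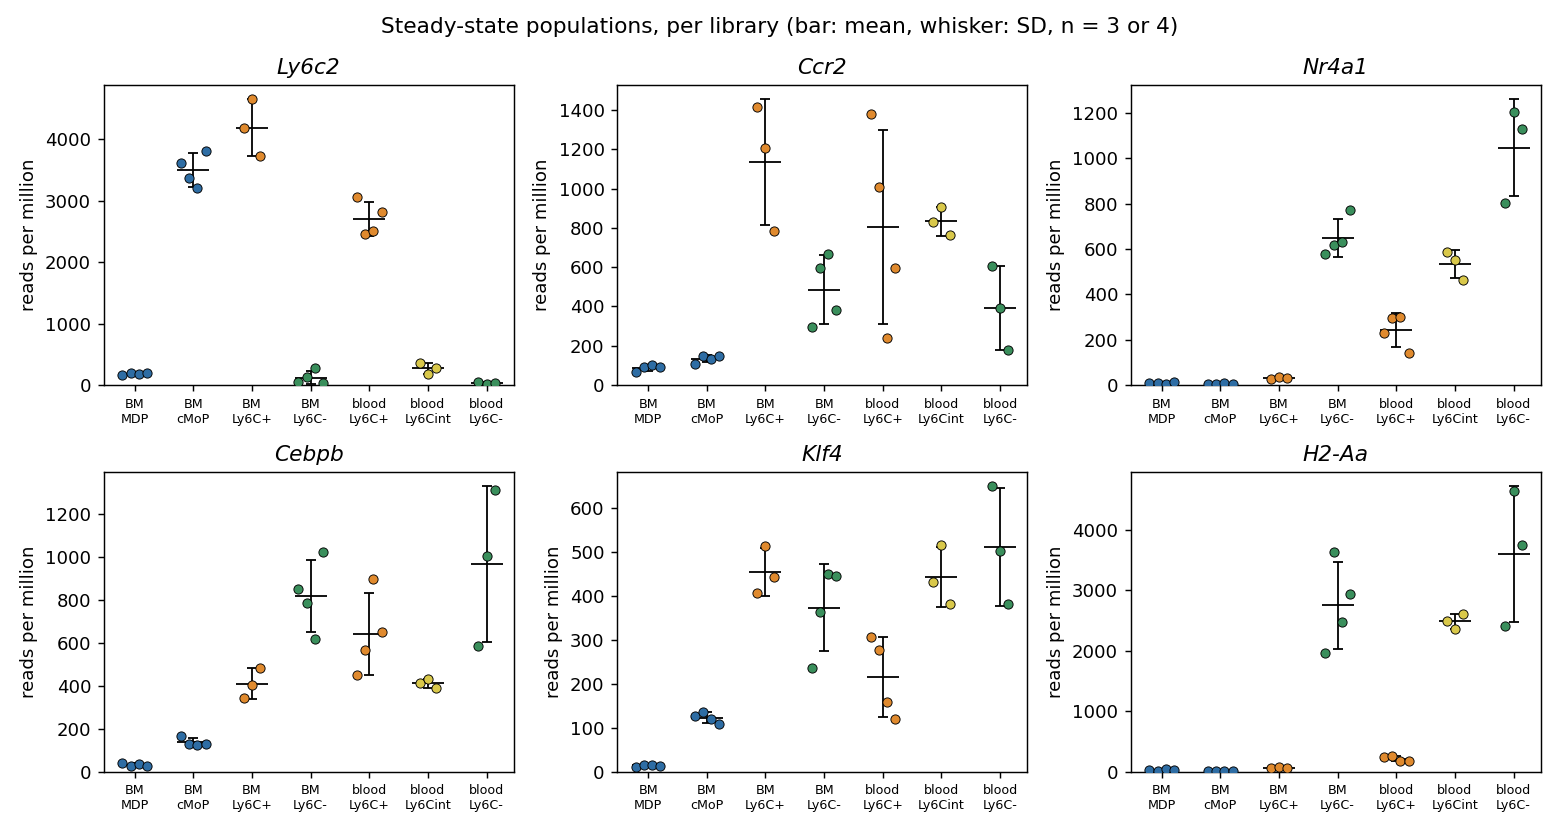
Expression in RPM of 6 genes in the 7 populations of the 7-week table, on linear axes from 0. Points are libraries, bars are means and whiskers are SD (n = 3 or 4). Nr4a1 averaged 1047 in blood Ly6C- monocytes and 30.6 in marrow Ly6C+ monocytes.

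The step from MDP to cMoP is the commitment of a marrow progenitor to the monocyte line. Ly6c2, a gene of the sorted antigen, averaged 3504 ± 271 (n = 4) in cMoP and 181 ± 16.9 (n = 4) in MDP, a log2 ratio of 4.27 ± 0.38. Fcgr3, a receptor for IgG, rose by 4.28 ± 0.14, Elane, the neutrophil elastase of primary granules, by 4.25 ± 0.60, and Ms4a3, a membrane protein of granulocyte and monocyte progenitors, by 4.15 ± 0.53. Flt3, the receptor that sustains dendritic cell progenitors, averaged 9.01 ± 3.80 in cMoP and 258 ± 14.9 in MDP. Dntt, the DNA polymerase of early lymphoid cells, fell by 6.03 ± 0.46, and Nrgn, Aff3 and Tspan13 fell by 4.27, 3.22 and 3.06. Cebpb, the transcription factor removed in the ko mice, rose by 2.01 ± 0.21 (136 ± 18.9 against 33.2 ± 5.83, adjusted p = 2.91e-08), with Cebpd at 1.59 and Klf4 at 3.03.

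Among the gene lists, 13 of 18 progenitor genes fell from MDP to cMoP (13 adjusted over the list alone, adjusted p = 0.00274 with an estimated correlation), among them Flt3, Sox4 (-2.66) and Egfl7 (-2.68). Of 14 primary granule genes 9 rose (11 adjusted over the list alone, adjusted p = 0.00632 with an estimated correlation), including Fcnb (3.59) and Igsf6 (2.12). Also, 7 of 15 Ly6C+ monocyte genes rose (7 adjusted over the list alone, adjusted p = 0.0154 with an estimated correlation), including Hp (2.61) and Mgst1 (2.75). Markers of plasmacytoid dendritic cells and basophils fell in 5 of 7 cases (6 adjusted over the list alone, adjusted p = 0.00214 with an estimated correlation), among them Runx2 (-2.36), Tcf4 (-1.68) and Cox6a2 (-3.56). Of 17 MHC class II and dendritic cell genes 6 fell and 1 rose (9 and 1 adjusted over the list alone), a call lost at adjusted p = 0.0576 with an estimated correlation. The cell cycle list was not called (camera adjusted p = 0.56). In all, limma called 1052 of 11373 genes, 591 higher and 461 lower in cMoP. With array weights the count was 3252, and in a fit of these 8 libraries alone it was 2616.

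From cMoP to marrow Ly6C+ monocytes, the monocyte was set against the progenitor of the same tissue. Fn1, fibronectin, averaged 1381 ± 97.6 (n = 3) in monocytes and 19.3 ± 3.17 (n = 4) in cMoP (log2 ratio 6.10 ± 0.27), and Chil3, a chitinase-like secreted protein, 1512 ± 354 against 34.8 ± 6.65 (5.39 ± 0.32). Slfn1 (6.29), Clec4a1 (6.13), Plbd1 (5.98), Fgr (5.60), a Src family kinase, and Pirb (5.26), an inhibitory receptor, rose as well. Ccr2, the chemokine receptor for leaving the marrow, rose by 3.03 ± 0.39 (1136 ± 321 against 135 ± 19), Cebpb by 1.58 ± 0.23 (410 ± 70.9 against 136 ± 18.9) and Klf4 by 1.88 ± 0.25. Kit, the stem cell factor receptor, fell by 3.97 ± 0.54, and Nkg7, Hdc and Ms4a3 fell by 4.24, 3.97 and 3.81.

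Interferon response genes rose in 32 of 35 cases (32 adjusted over the list alone, adjusted p = 0.00632 with an estimated correlation), led by Ifi27l2a (5.74), Irf7 (4.60), the transcription factor of interferon induction, and Rtp4 (4.70). Rising lists also included NF-kappaB inflammatory genes, 15 of 19 (16 adjusted over the list alone, adjusted p = 0.00274 with an estimated correlation). Adhesion and chemotaxis receptors rose in 14 and fell in 4 of 27 cases (15 and 4 adjusted over the list alone, adjusted p = 0.00177 with an estimated correlation), with the integrins Itgam (3.81) and Itgb2 (3.17). Complement and scavenger genes went up in 12 and down in 1 of 21 cases (13 and 1 adjusted over the list alone, adjusted p = 0.00632 with an estimated correlation), with the scavenger receptor Msr1 (5.02) and Cd68 (2.74). Progenitor genes fell in 14 of 18 cases (14 adjusted over the list alone, adjusted p = 0.0286 with an estimated correlation), with Erg (-3.10) and Myc (-3.54). Of 14 primary granule genes 11 fell and 1 rose (11 and 1 adjusted over the list alone, adjusted p = 0.114 with an estimated correlation). Of 69 ribosomal protein genes 45 fell (47 adjusted over the list alone, adjusted p = 0.153 with an estimated correlation). Limma called 4286 genes, 1737 higher and 2549 lower, while edgeR with TMM called 2361 higher and 2137 lower, and scaling to the listed genes 1784 and 2505. The median of all genes was -0.17, against -0.07 with quantile scaling, and relative to it Cebpb stood at 1.74.

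Blood Ly6C+ monocytes were compared with those of marrow to show what changes as the cells leave. Every one of 39 cell cycle genes was lower in blood (39 adjusted over the list alone, adjusted p = 0.00797 with an estimated correlation), for example Top2a, the topoisomerase of dividing cells, at 16.5 ± 12.8 (n = 4) against 433 ± 51.1 (n = 3), and Ccna2, cyclin A2, at 8.24 ± 7.35 against 244 ± 26.9. Nr4a1, the nuclear receptor needed for Ly6C- monocytes, rose by 2.89 ± 0.29 (242 ± 74.3 against 30.6 ± 5.39), and Ace, angiotensin converting enzyme, by 3.18 ± 0.24. Socs3 (4.04) and Dusp1 (3.73), inhibitors of cytokine and kinase signalling, Il1b (3.37) and Ccl5 (3.35) rose too. Cebpb stood at 640 ± 189 against 410 ± 70.9 (log2 ratio 0.61 ± 0.22, adjusted p = 0.0445), a call that was lost under 9 alternatives, and Klf4 fell by 1.17 ± 0.25.

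Ly6C- monocyte genes were up in 21 and down in 1 of 24 cases in blood Ly6C+ cells against marrow Ly6C+ cells (21 and 1 adjusted over the list alone, adjusted p = 1.13e-05 with an estimated correlation), including Gngt2 (2.65) and Treml4 (2.56). Immediate early genes rose in 15 of 20 cases (16 adjusted over the list alone, adjusted p = 0.0124 with an estimated correlation), with Fos at 1.97. Interferon response genes rose in 20 and fell in 1 of 35 cases (23 and 1 adjusted over the list alone, adjusted p = 0.0344 with an estimated correlation). Genes of MHC class II and dendritic cells rose in 9 of 17 cases (10 adjusted over the list alone, adjusted p = 0.0173 with an estimated correlation), with H2-Aa at 1.65. The neutrophil markers S100a8 and S100a9 fell by 4.40 and 4.63, but their list was not called as a whole and another member rose. Limma called 2959 genes, 833 higher and 2126 lower, but quantile scaling gave 1461 and 1370, and edgeR 1309 and 1440, while scaling to the listed genes left 927 and 1983. The median of all genes was -0.19 (0.06 with quantile scaling), and relative to it Cebpb stood at 0.80 and Klf4 at -0.98. A fit of these libraries alone called 1415.

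The Ly6Cint cells of blood were compared with Ly6C+ cells as the stage between the classical and patrolling types. Ly6c2 averaged 273 ± 89.7 (n = 3) in Ly6Cint and 2709 ± 277 (n = 4) in Ly6C+ cells (log2 ratio -3.36 ± 0.42). Cd300e, an activating receptor of monocytes, averaged 99.8 ± 30.8 against 2.26 ± 0.52 (4.91 ± 0.34). Cd36, the fatty acid scavenger receptor, rose by 4.14, Eno3, a muscle-type enolase, by 3.76, Itgax, the integrin CD11c, by 3.73 and Bcl2a1d, a survival factor, by 4.44. Nr4a1 rose by 1.19 ± 0.29 (534 ± 62.9 against 242 ± 74.3), a call that ended with array weights, while Klf4 rose by 1.13 ± 0.25 and Cebpd fell by 1.40 ± 0.20. Cebpb was 411 ± 21.9 against 640 ± 189 (-0.59 ± 0.22, adjusted p = 0.0498), a call that was lost under 15 alternatives. In wt blood of the knockout table Cebpb went the other way. There it averaged 1488 ± 348 in Ly6Cint and 749 ± 78.3 in Ly6C+ cells (n = 2 each), a difference that was not tested.

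Of 24 Ly6C- monocyte genes 20 rose and 1 fell in Ly6Cint against Ly6C+ cells (20 and 1 adjusted over the list alone, adjusted p = 1.22e-06 with an estimated correlation). Of 15 Ly6C+ monocyte genes 11 fell (11 adjusted over the list alone, adjusted p = 0.0356 with an estimated correlation). MHC class II and dendritic cell genes rose in 9 of 17 cases (9 adjusted over the list alone, adjusted p = 0.0186 with an estimated correlation), with H2-Aa (3.52), H2-Eb1 (3.72) and H2-Ab1 (3.56), the chains that present peptides to T cells. Interferon response genes fell in 19 of 35 cases (19 adjusted over the list alone), among them Ifit3 (-2.24), but the list call was lost at adjusted p = 0.229 with an estimated correlation. Limma called 3092 genes, 904 higher and 2188 lower, whereas quantile scaling gave 1194 and 1355, edgeR 939 and 1042, and scaling to the listed genes 1240 and 1405. The median of all genes was -0.21 (-0.05 with quantile scaling), and relative to it Nr4a1 stood at 1.40 and Cebpb at -0.38. Array weights gave 1562 calls, and a fit of these libraries alone 675.

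From Ly6Cint to Ly6C- blood cells some genes of the classical cells fell. Chil3 averaged 29.5 ± 8.04 (n = 3) against 741 ± 66.2 (n = 3), a log2 ratio of -4.63 ± 0.34, and Ly6c2 fell by 3.35 ± 0.44. Cd300e rose further, by 2.57 ± 0.37 (623 ± 301 against 99.8 ± 30.8), with Mgl2 (3.23), a galactose-binding lectin, Cd83 (1.92), an activation antigen, and Pecam1 (2.23), an endothelial adhesion molecule. Cebpb rose by 1.15 ± 0.24 (965 ± 364 against 411 ± 21.9, adjusted p = 0.00435), a call that ended without Ly6C- replicate 3 and in a fit of the compared libraries alone. Ly6C- monocyte genes rose in 10 of 24 cases (13 adjusted over the list alone, adjusted p = 0.00632 with an estimated correlation), such as Cd9 (1.88) and Pparg (1.71). Ly6C+ monocyte genes fell in 6 of 15 (9 adjusted over the list alone, adjusted p = 0.0181 with an estimated correlation). Ribosomal protein genes fell in 12 of 69 (21 adjusted over the list alone, adjusted p = 0.0128 with an estimated correlation). Interferon response genes fell in 6 and rose in 1 of 35 cases (8 and 1 adjusted over the list alone), a call lost at adjusted p = 0.0718 with an estimated correlation. Limma called 1009 genes, 825 higher and 184 lower, while quantile scaling gave 315 and 286, edgeR 249 and 166, and scaling to the listed genes 458 and 270. The median of all genes was 0.20 (0.01 with quantile scaling), and relative to it Cebpb stood at 0.95. The count was 1937 without Ly6C- replicate 1, 298 without replicate 2, 251 without replicate 3 and 644 without Ly6Cint replicate 1, and a fit of these 6 libraries alone called 1.

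Over the whole course, blood Ly6C- cells were set against blood Ly6C+ cells. Ly6c2 averaged 30.1 ± 21.8 (n = 3) against 2709 ± 277 (n = 4), a log2 ratio of -6.71 ± 0.42, and Cd300e rose by 7.48 ± 0.34. Lilra5 (5.65), Dusp16 (5.64), Fabp4 (5.32), a fatty acid carrier, Itgax (5.28), Cd36 (5.14) and Tgm2 (4.87), a transglutaminase, rose, and so did H2-Eb1 (4.77), Pparg (3.67), the lipid-sensing nuclear receptor, and Bcl2 (3.42), the survival factor. Mmp8 (-5.67), a collagenase, F13a1 (-4.42), a coagulation factor subunit, and the chemokine Cxcl10 (-4.48) fell. Nr4a1 rose by 2.15 ± 0.29 and Cebpd fell by 1.59 ± 0.20, while Cebpb had a log2 ratio of 0.56 ± 0.22 (adjusted p = 0.0781).

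Among Ly6C- monocyte genes 22 of 24 rose (22 adjusted over the list alone, adjusted p = 6.07e-07 with an estimated correlation). Of 15 Ly6C+ monocyte genes 11 fell and 1 rose (13 and 1 adjusted over the list alone, adjusted p = 0.00292 with an estimated correlation). Interferon response genes fell in 24 of 35 cases (28 adjusted over the list alone, adjusted p = 0.02 with an estimated correlation), with Isg15 at -3.05. Adhesion and chemotaxis receptors rose in 14 and fell in 3 of 27 (15 and 6 adjusted over the list alone, adjusted p = 0.00632 with an estimated correlation), with Cd9 (4.15) and S1pr5 (2.77). For MHC class II and dendritic cells, 8 of 17 genes rose and 1 fell (8 and 2 adjusted over the list alone), a call lost at adjusted p = 0.153 with an estimated correlation. Limma called 2310 genes, 1121 higher and 1189 lower in Ly6C- cells, and 719 in a fit of these libraries alone.

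In marrow, the Ly6C- cells were set against Ly6C+ cells in the same way. All 39 cell cycle genes were lower (39 adjusted over the list alone, adjusted p = 0.0286 with an estimated correlation), and Fn1 averaged 27.9 ± 14.1 (n = 4) against 1381 ± 97.6 (n = 3). Cd300e (7.38 ± 0.34), Fabp4 (7.06), Pltp (6.09), a phospholipid carrier, Fcgr4 (5.90), a receptor for IgG, and Il1b (5.73) rose. Nr4a1 averaged 650 ± 83.7 against 30.6 ± 5.39 (4.37 ± 0.29), and Cebpb 818 ± 168 against 410 ± 70.9 (0.99 ± 0.22, adjusted p = 0.000785), while Irf8, a factor of mononuclear phagocyte fate, fell by 1.80 ± 0.26. F13a1 (-5.60) and Elane (-5.64) fell.

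Ly6C- monocyte genes rose in 23 of 24 cases in marrow Ly6C- cells (23 adjusted over the list alone, adjusted p = 3.31e-07 with an estimated correlation). MHC class II and dendritic cell genes rose in 9 and fell in 2 of 17 (10 and 3 adjusted over the list alone, adjusted p = 0.02 with an estimated correlation). Monocyte transcription factors rose in 18 and fell in 6 of 34 (18 and 6 adjusted over the list alone, adjusted p = 0.0157 with an estimated correlation). Apoptosis regulators rose in 8 and fell in 5 of 24 cases (10 and 5 adjusted over the list alone, adjusted p = 0.0491 with an estimated correlation). Markers of tissue macrophages were higher in 8 of 12 cases (9 adjusted over the list alone, adjusted p = 0.00668 with an estimated correlation), including Vcam1 (2.39) and C1qb (2.92). Haemoglobin genes rose too, and erythroid markers were higher in 6 of 9 cases (6 adjusted over the list alone, adjusted p = 0.317 with an estimated correlation). Ly6C+ monocyte genes fell in 11 and rose in 1 of 15 (12 and 2 adjusted over the list alone), a call lost at adjusted p = 0.0678 with an estimated correlation. Limma called 4565 genes, 1256 higher and 3309 lower, while quantile scaling gave 2027 and 2205, edgeR 1856 and 2103, and scaling to the listed genes 1605 and 2666. The median of all genes was -0.28 (0.02 with quantile scaling), and relative to it Cebpb stood at 1.27.

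The knockout table asks what blood monocytes lose without C/EBPb. Cebpb itself was read in every library: 804 and 693 in the wt Ly6C+ cells, 115 and 57.2 in the ko Ly6C+ cells, 1734 and 1242 in the wt Ly6Cint cells, 186 and 67.1 in the ko Ly6Cint cells, and 1936 and 1549 in the wt Ly6C- cells. The files do not say which part of the gene was deleted. The ko libraries held Xist, the RNA of the inactive X chromosome, at 63.3 to 121.5 and the wt blood libraries at no more than 1.667, with the Y-linked gene Ddx3y at 26.88 to 73.01 in wt, so sex and genotype coincide in these libraries.

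**Figure D2:**
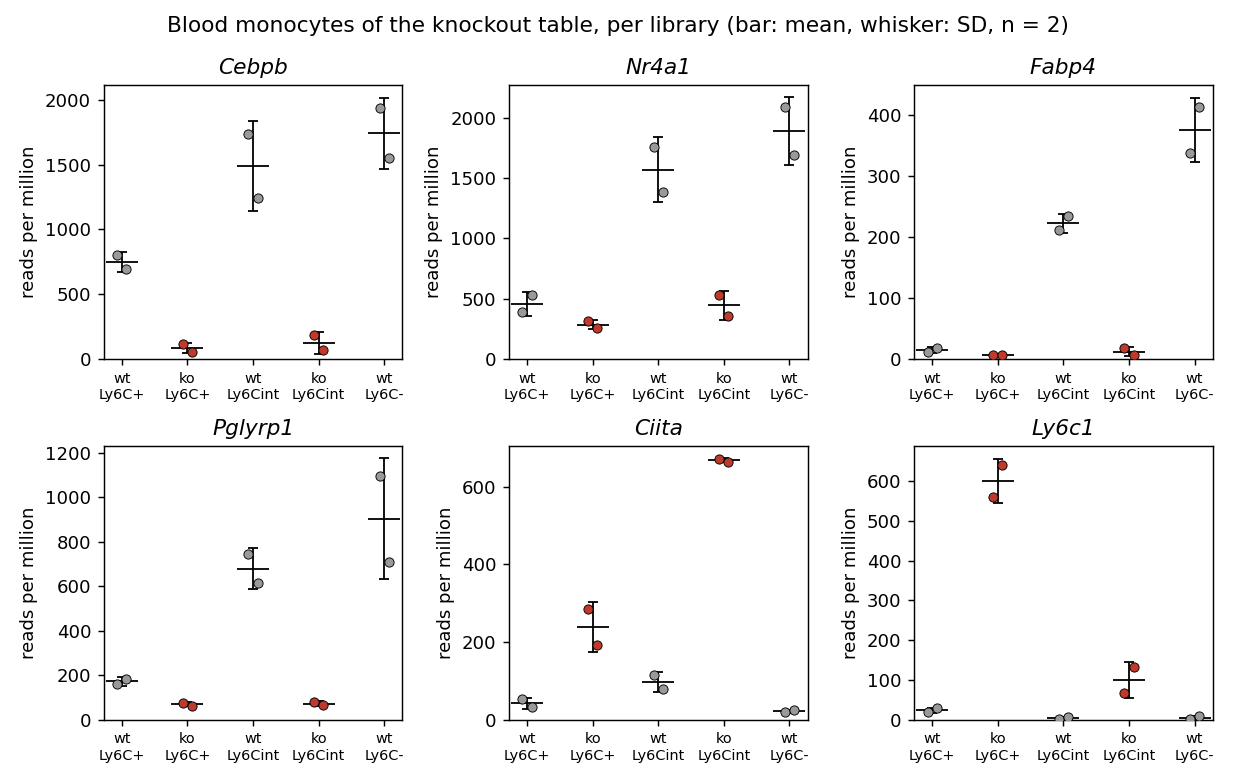
Expression in RPM of 6 genes in the blood libraries of the knockout table, on linear axes from 0. Points are libraries, bars are means and whiskers are SD (n = 2), with ko in red. Fabp4 averaged 222 in wt and 12.3 in ko Ly6Cint cells, and Ciita 97.0 and 668.

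In Ly6Cint monocytes the ko libraries had lower levels of genes that mark the Ly6C- fate. Ly6c2, which falls toward that fate, averaged 409 ± 87 in ko and 139 ± 64.3 in wt (n = 2 each). Its log2 ratio was 1.61 ± 0.50 (adjusted p = 0.0728 by limma). A larger share of cells from other sort gates in the ko libraries stays open for the Ly6C- genes. Fabp4 averaged 12.3 ± 7.51 (n = 2) in ko and 222 ± 16.1 (n = 2) in wt, a log2 ratio of -4.19 ± 0.40, and Pglyrp1, a peptidoglycan-binding antibacterial protein, 72.2 ± 10.6 against 679 ± 91.4 (-3.22 ± 0.25). Nr4a1 fell by 1.83 ± 0.26 (446 ± 121 against 1569 ± 267, adjusted p = 0.000765), Bcl2 by 2.04 ± 0.30, Ace by 2.11 ± 0.23 and S1pr5, the receptor for egress along sphingosine phosphate, by 2.42 ± 0.44. Tgm3 (-3.30), Chil1 (-3.27), Ip6k3 (-3.70) and Rpl26 (-3.80) fell, and Xist (5.78), Emp1 (5.47), Ifi44l (5.05), Ly6c1 (4.46) and Lmna (4.29), a nuclear lamin, rose. Cebpa, the related factor of myeloid progenitors, averaged 189 ± 22.7 against 64.7 ± 15.5 (1.55 ± 0.23, adjusted p = 0.000976).

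Of 24 Ly6C- monocyte genes 12 fell in ko Ly6Cint cells (20 adjusted over the list alone, adjusted p = 0.0038 with an estimated correlation), including Apoc2 (-3.00) and the integrin Itgal (-1.81). Adhesion and chemotaxis receptors fell in 8 and rose in 1 of 28 cases (12 and 2 adjusted over the list alone, adjusted p = 0.0313 with an estimated correlation). Interferon response genes rose in 9 of 35 (16 adjusted over the list alone, adjusted p = 0.0429 with an estimated correlation), among them Ifi44 (4.52) and Isg15 (2.00). Class II and dendritic cell genes rose in 8 of 17 (14 adjusted over the list alone), a call lost at adjusted p = 0.0579 with an estimated correlation. H2-DMa and H2-DMb1, which load peptides, rose by 1.76 and 2.16. Ciita, the transactivator of the class II genes, chosen after its values were seen, rose by 2.80 ± 0.56. Markers of tissue macrophages rose in 6 of 12 (6 up and 1 down adjusted over the list alone, adjusted p = 0.0647 with an estimated correlation), with Cd163 (2.56) and C1qb (3.68). Of 15 Ly6C+ monocyte genes 2 rose and 4 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.468), the list's median being -0.36 and its mean 0.12. The risers were Ly6c1 and F13a1 (2.61 ± 0.52), and Hp (-1.88) and Mgst1 (-1.21) were among those that fell.

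Limma called 721 of 11388 genes in Ly6Cint cells, 413 higher and 308 lower in ko, and edgeR called 948, 422 higher and 526 lower. A fit of these 4 libraries alone called 0 genes (2094 had an unadjusted p under 0.05 in the fit of the whole table), and the count was 375 without ko replicate 1 and 224 without ko replicate 2.

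In Ly6C+ monocytes fewer genes passed the test. Ly6c1, the sister gene of Ly6c2, averaged 600 ± 56.1 (n = 2) in ko and 23.8 ± 6.82 (n = 2) in wt, a log2 ratio of 4.63 ± 0.62, beside Ly6c2 at 0.26 ± 0.50 (adjusted p = 0.99). Ifi44l (5.92), Ifi44 (4.98), Emp1 (4.73), Arsb (3.77), a lysosomal sulfatase, Folr2 (3.96), a folate receptor, and C3ar1 (3.18), the receptor for complement C3a, rose. Rpl26 (-3.95), Vcan (-2.81), a matrix proteoglycan, Saa3 (-3.48) and Ace (-1.67) fell. Cx3cr1, the fractalkine receptor, fell by 1.34 ± 0.31 (adjusted p = 0.0499) and Cebpa rose by 1.01 ± 0.23 (adjusted p = 0.0482), calls that 11 alternatives ended in each case.

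In ko Ly6C+ cells 3 of 24 Ly6C- monocyte genes fell (6 down and 1 up adjusted over the list alone, adjusted p = 0.0392 with an estimated correlation). Complement and scavenger genes rose in 5 of 21 cases (8 up and 1 down adjusted over the list alone, adjusted p = 0.0489 with an estimated correlation). Markers of tissue macrophages rose in 4 of 12 (6 adjusted over the list alone, adjusted p = 0.0242 with an estimated correlation), among them C1qb (3.69) and Mrc1 (2.26), whose calls 8 and 7 alternatives ended. Class II and dendritic cell genes rose in 4 of 17 (12 adjusted over the list alone), a call lost at adjusted p = 0.0831 with an estimated correlation. Interferon response genes had a preset-correlation call with 1 riser, Ifi44 (3 up and 1 down adjusted over the list alone), lost at adjusted p = 0.171 with an estimated correlation. Limma called 144 genes, 91 higher and 53 lower, and edgeR 131. Array weights gave 351, and a fit of these 4 libraries alone 0 (1091 at an unadjusted p under 0.05 in the whole table). The count was 73 and 43 without ko replicate 1 or 2, and 34 and 38 without wt replicate 1 or 2.

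The ko effect itself differed between Ly6Cint and Ly6C+ cells for 1 gene by limma, Capg, an actin-capping protein, with a difference of 1.68 ± 0.23 (adjusted p = 0.0294, 677 genes at an unadjusted p under 0.05). Capg was chosen after its values were seen, as the only call, and 7 alternatives ended it. The count was 0 without ko Ly6Cint replicate 2, either ko Ly6C+ library or either wt Ly6C+ library, 2 without Ly6Cint replicate 1 of ko or of wt, and 3 without wt Ly6Cint replicate 2. EdgeR called 8, and the fit of the 8 compared libraries alone and limma without trend called 0 each. As a list, the Ly6C- monocyte genes were more reduced in Ly6Cint cells, with a median difference of -0.89 (8 down adjusted over the list alone, adjusted p = 0.0121 with an estimated correlation). Members that start lower in wt Ly6C+ than wt Ly6Cint cells, as Fabp4 did (14.55 against 222 RPM), had less room to fall there. For the interferon (1 up adjusted over the list alone), MHC class II and adhesion lists (4 down) the difference was lost at adjusted p = 0.19, 0.382 and 0.0742 with an estimated correlation. Between both ko comparisons 73 genes rose and 37 fell in common, against 3.3 and 1.43 for independent calls. Opposite ways moved 1 gene, against 4.38 (r = 0.55 across 11388 genes). The calls are not independent, since both comparisons share replicate numbers and the sex difference between ko and wt, so the overlap need not reflect the genotype. Against the steady Ly6C- minus Ly6C+ change, 268 genes moved the opposite way in ko Ly6Cint cells, where independence would give 71, and 36 and 23 rose and fell alike, where it would give 38.1 and 32.2.

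In the wt mice of this table, Ly6C- cells differed from Ly6C+ cells in Cd300e (log2 ratio 6.43 ± 0.42, 1094 ± 90 against 11.7 ± 0.29, n = 2 and 2), Cd9 (5.41), Ikzf3 (5.26), a lymphoid zinc finger factor, Fabp4 (4.62) and Cd83 (4.54), which rose, and in Ly6c2 (-5.52), Fn1 (-5.48) and Vcan (-4.72), which fell. Cebpb averaged 1742 ± 274 against 749 ± 78.3 (1.21 ± 0.38, adjusted p = 0.0543), and Nr4a1 rose by 2.05 ± 0.26. Of 24 Ly6C- monocyte genes 21 rose (21 adjusted over the list alone, adjusted p = 0.00255 with an estimated correlation). Of 15 Ly6C+ monocyte genes 12 fell (12 down and 1 up adjusted over the list alone, adjusted p = 0.0396 with an estimated correlation). Interferon response genes fell in 19 of 35 (24 adjusted over the list alone, adjusted p = 0.0171 with an estimated correlation). Here MHC class II and dendritic cell genes fell in 8 of 17 cases (9 adjusted over the list alone), a call lost at adjusted p = 0.215 with an estimated correlation. Limma called 1198 genes, 551 higher and 647 lower, with 2149 by array weights and 739 in a fit of these libraries alone. The count was 630 and 732 without Ly6C- replicate 1 or 2, and 640 and 616 without Ly6C+ replicate 1 or 2.

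The Ly6C- minus Ly6C+ change was set side by side in the 3 independent sets of libraries. Across genes, which are not independent replicates, Pearson's r was 0.697 between the 7-week and wt blood (Spearman's rho 0.567), 0.595 between the 7-week and host blood (0.497) and 0.71 between wt and host blood (0.604). The 7-week and wt calls shared 363 genes that rose, where independence gives 53.2, and 474 that fell, where it gives 68.7.

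A signature of 100 genes up and 100 down in the 7-week blood Ly6C- minus Ly6C+ comparison placed each library on an axis from 0 (mean Ly6C+ library of its own table and tissue) to 100 (mean Ly6C- library). The ko Ly6Cint libraries stood at 40.6 and 33.5 and the wt Ly6Cint libraries at 70.8 and 69.6, while the ko Ly6C+ libraries stood at -2.73 and -8.57. With 2 against 2 libraries an exact test cannot go below p = 0.33, so these are values only. More Ly6C+ cells in the ko Ly6Cint sort would also lower the position, and this stays open. The signature holds Ly6c1, which was higher in ko. It also holds class II genes such as H2-Aa and H2-Ab1, not called between wt Ly6C- and Ly6C+ cells (log2 ratios 0.39 and 0.17). The signature of the host blood in place of the 7-week one gave mean positions of 16.6 for ko and 66.4 for wt Ly6Cint cells, and -14.6 for ko Ly6C+ cells.

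**Figure D3:**
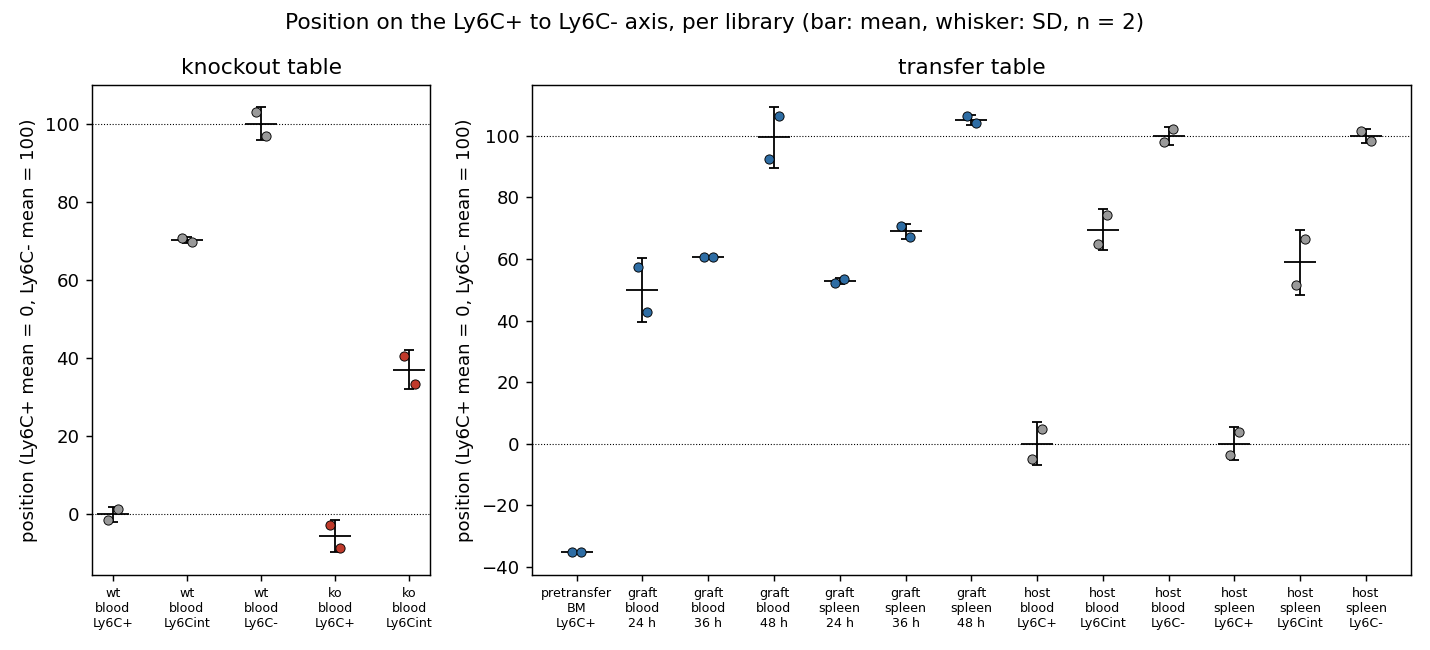
Position of each library between the mean Ly6C+ library (0) and the mean Ly6C- library (100) of its own table and tissue. Points are libraries, bars are means and whiskers are SD (n = 2). The ko Ly6Cint libraries sit at 33.5 and 40.6, below the wt Ly6Cint libraries at 69.6 and 70.8, and graft blood stands at 42.7 and 57.3 after 24 h and at 92.5 and 106.4 after 48 h.

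The transfer experiment follows marrow Ly6C+ monocytes placed in other mice. On the signature axis the graft libraries of blood stood at 42.7 and 57.3 after 24 h, at 60.8 in both after 36 h and at 92.5 and 106.4 after 48 h, and those of spleen at 52.3 and 53.7, 67.2 and 70.7, and 104.1 and 106.4. Over hours after transfer Pearson's r was 0.917 in blood and 0.974 in spleen, and Spearman's rho 0.956 in both (n = 6 each, exact permutation p = 0.0222, two-sided, the smallest it can be, adjusted p = 0.0222 over both tissues). Without the pair of libraries farthest from the median time r was 0.722 to 0.982 in blood and 0.957 to 0.997 in spleen. The time points were prepared as separate libraries, and no batch label is given to recompute within. Before transfer the cells stood at -35.2 on the blood axis, which compares a marrow with a blood population.

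After 24 h in blood the transferred cells had changed in many genes. Nr4a1 averaged 1009 ± 44.6 (n = 2) against 55.4 ± 0.31 (n = 2) before transfer (log2 ratio 4.16 ± 0.24), Cebpb 2061 ± 417 against 791 ± 20.1 (1.37 ± 0.20, adjusted p = 5.56e-05), and Ly6c2 634 ± 208 against 4223 ± 302 (-2.77 ± 0.44). Cd300e and Tgm3, listed at 0 before transfer, averaged 208 ± 80.9 and 136 after it. Cdca3, Ccna2 and Elane, at 164, 113 ± 25.7 and 94.9 ± 1.55 before transfer, were listed at 0 after it. Klf4 rose by 1.30 ± 0.24 and Ccr2 fell by 2.09 ± 0.46.

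Ly6C- monocyte genes rose in 23 of 24 cases 24 h after transfer (24 adjusted over the list alone, adjusted p = 0.00029 with an estimated correlation), with Ace (4.58), Eno3 (5.43) and Pou2f2 (2.59). Cell cycle genes fell in 32 of 39 (36 adjusted over the list alone, adjusted p = 0.00029 with an estimated correlation), with Tpx2 at -6.15. Immediate early genes rose in 14 of 23 (15 adjusted over the list alone, adjusted p = 0.00141 with an estimated correlation), with Jun (3.44) and Fos (3.01). Primary granule genes fell in 8 and rose in 1 of 12 (8 and 1 adjusted over the list alone, adjusted p = 0.0354 with an estimated correlation). Ly6C+ monocyte genes fell in 9 of 15 (10 down and 1 up adjusted over the list alone), a call lost at adjusted p = 0.171 with an estimated correlation. Haemoglobin genes were higher, Hba-a1 at 2448 ± 1180 against 13.6 ± 4.34, with 6 of 14 erythroid markers up (8 adjusted over the list alone, adjusted p = 0.118 with an estimated correlation). Limma called 1610 of 12096 genes, 361 higher and 1249 lower, and quantile scaling gave 512 and 619. The 24 h blood libraries list 8109 to 8278 genes above 0 and the pretransfer libraries 11574 to 11719. The median of all genes was -0.53 (0.03 with quantile scaling), and relative to it Cebpb stood at 1.89. Array weights gave 996, and the count was 639 without pretransfer replicate A and 658 without B.

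Between 24 and 48 h in blood part of the Ly6C+ monocyte genes fell further in the grafts. Ly6c2 averaged 48.0 ± 20.8 (n = 2) against 634 ± 208 (n = 2), a log2 ratio of -3.73 ± 0.44, and F13a1 (-7.15 ± 0.61), Ccr2 (-1.85) and Axl (-5.00), a receptor for dying cells, fell. Adrb1, the beta-1 adrenergic receptor, averaged 123 ± 22.6 against 0.66 ± 0.93 and Cd36 rose by 1.87 ± 0.54, a call that 7 alternatives ended, while Cebpb had a log2 ratio of 0.59 ± 0.20 (adjusted p = 0.066). Ly6C+ monocyte genes fell in 7 of 15 cases (8 down and 1 up adjusted over the list alone, adjusted p = 0.02 with an estimated correlation). Among Ly6C- monocyte genes 5 of 24 rose (10 adjusted over the list alone, adjusted p = 0.127 with an estimated correlation). MHC class II and dendritic cell genes fell in 6 of 20 (8 adjusted over the list alone, adjusted p = 0.255 with an estimated correlation), with H2-Ab1 at -2.17. Limma called 979 genes, 535 higher and 444 lower, but array weights called 9 and a fit of these 4 libraries alone 7, none of them shared, and the count was 1672 without 48 h replicate AC.

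In spleen the same interval gave Ly6c2 at a mean of 71.4 (n = 2) against 869 ± 361 (n = 2), a log2 ratio of -3.55 ± 0.44, with F13a1 (-5.63) and Irf8 (-1.09) falling and Dusp1 (4.39), Adrb1 (4.20) and Cd36 (2.27) rising. Ly6C+ monocyte genes fell in 7 of 15 cases (9 adjusted over the list alone, adjusted p = 0.02 with an estimated correlation). Only 2 of 24 Ly6C- monocyte genes rose (10 adjusted over the list alone, adjusted p = 0.0307 with an estimated correlation). Interferon response genes fell in 6 of 35 (19 adjusted over the list alone), with Oasl1 at 48.6 ± 0.62 after 24 h and listed at 0 after 48 h, but the list call was lost at adjusted p = 0.118 with an estimated correlation. Markers of tissue macrophages fell in 3 of 15 (9 adjusted over the list alone, adjusted p = 0.159 with an estimated correlation). The 48 h libraries list 8396 to 8614 genes above 0 and those of 24 h 9354 to 10970. Limma called 292 genes, 38 higher and 254 lower, and quantile scaling 54 and 133 around a median that moved from -0.17 to 0.02. Array weights called 12 and a fit of these libraries alone 0 (1957 at an unadjusted p under 0.05 in the whole table), and the count was 73 without 24 h replicate C, 545 without 24 h B, 688 without 48 h C and 482 without 48 h B.

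Averaged over the 3 times, grafts in spleen differed from those in blood in immediate early genes. Fos averaged 48.6 ± 39.9 (n = 6) in spleen and 671 ± 217 (n = 6) in blood, a log2 ratio of -4.16 ± 0.21, with Dusp1 (-3.49), Jun (-1.92) and Zfp36 (-1.53) lower too. In all, 11 of 23 immediate early genes fell (14 adjusted over the list alone, adjusted p = 0.00177 with an estimated correlation). B cell markers were higher in spleen in 7 of 12 cases (12 adjusted over the list alone, adjusted p = 0.0138 with an estimated correlation). T and NK cell markers were higher in 4 of 21 (12 adjusted over the list alone, adjusted p = 0.0154 with an estimated correlation), and tissue macrophage markers in 9 of 15 (13 adjusted over the list alone, adjusted p = 0.0124 with an estimated correlation). Examples are Cd8b1, at 48.9 ± 20.9 in spleen and listed at 0 in blood, Cd79b (1.53) and Vcam1 (5.03). Cebpb was 1721 ± 333 against 2399 ± 694 (-0.46 ± 0.11, adjusted p = 0.026), a call that 8 alternatives ended. Erythroid markers fell in 7 and rose in 1 of 14 cases (7 and 2 adjusted over the list alone, adjusted p = 0.199 with an estimated correlation). Limma called 458 genes, 351 higher and 107 lower in spleen, and quantile scaling 126 and 96 around a median that moved from 0.16 to -0.01. Array weights called 26 and a fit of these 12 libraries alone 57. The count was 217 and 234 without blood 36 h AC or B, 283 without spleen 36 h C, 1043 without blood 48 h AC, 806 and 774 without blood 24 h AC or B, and 782 and 733 without spleen 48 h B or C.

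After 48 h the blood grafts were set against each host population, whose cells were taken 24 h after transfer, so time differs too. The grafts list 7734 to 8761 genes above 0. Host blood Ly6C+, Ly6Cint and Ly6C- cells list 10802 to 11079, 10389 to 10788 and 10451 to 10672. Against host Ly6C+ cells, F13a1 averaged 0.66 ± 0.93 (n = 2) against 1058 ± 50.8 (n = 2), Ly6c2 fell by 5.58 ± 0.44, Cebpb rose by 1.43 ± 0.20 and Nr4a1 by 1.34 ± 0.24. Ly6C- monocyte genes were higher in 22 of 24 cases (22 adjusted over the list alone, adjusted p = 0.00141 with an estimated correlation). Ly6C+ monocyte genes were lower in 10 of 15 (11 adjusted over the list alone, adjusted p = 0.0101 with an estimated correlation). Limma called 1213 genes, 323 higher and 890 lower, and quantile scaling 392 and 526 around a median that moved from -0.40 to 0.05, relative to which Cebpb stood at 1.83. Array weights called 514 and a fit of these libraries alone 492, and the count was 346 and 534 without host replicate A or B.

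Against host Ly6Cint cells the grafts, with fewer genes above 0, had less of the class II program. Ciita averaged 1.75 ± 2.48 (n = 2) against 172 ± 123 (n = 2), H2-Eb1 fell by 3.57 ± 0.57 and Ccr2 by 2.80 ± 0.46, and MHC class II and dendritic cell genes fell in 6 of 20 cases (13 adjusted over the list alone, adjusted p = 0.0286 with an estimated correlation). H2-Aa, chosen after its values were seen, averaged 678 in grafts and 4200 in host Ly6Cint cells. In host Ly6C- and Ly6C+ cells it averaged 740 and 1250, nearer the grafts, while Ciita averaged 26.3 and 90.5 there. Just 2 of 24 Ly6C- monocyte genes rose (2 adjusted over the list alone, adjusted p = 0.229 with an estimated correlation). Limma called 360 genes, 41 higher and 319 lower, and quantile scaling 58 and 141 around a median that moved from -0.29 to 0.05. Array weights called 74 and a fit of these libraries alone 0 (2246 at an unadjusted p under 0.05 in the whole table), and the count was 54 without host replicate A, 196 without B and 1138 without 48 h AC.

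Against host Ly6C- cells, Chil3 averaged 192 ± 59.2 (n = 2) in grafts and 8.76 ± 6.82 (n = 2) in host cells (4.47 ± 0.46), while Chil1 (-5.32), Ciita (-3.33) and F13a1 (-2.34) fell, the calls of the last pair being ended by 9 alternatives each. The list of Ly6C- monocyte genes was not called (camera adjusted p = 0.798), and Ly6c2 had a log2 ratio of 1.35 ± 0.44 (adjusted p = 0.0894). Limma called 448 genes, 87 higher and 361 lower, and quantile scaling 116 and 149 around a median that moved from -0.31 to 0.05. Array weights called 92 and a fit of these libraries alone 281, and the count was 30 and 25 without host replicate A or B and 1209 without 48 h AC.

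The hosts' own cells, taken 24 h after transfer, gave a further pair of Ly6C- minus Ly6C+ comparisons. In blood, Cd300e averaged 1021 ± 128 (n = 2) against 19.1 ± 13.9 (n = 2), a log2 ratio of 5.86 ± 0.39, Chil3 and Ly6c2 fell by 7.31 and 6.94, and Cebpb rose by 1.28 ± 0.20 (adjusted p = 0.000262). In blood 22 of 24 Ly6C- monocyte genes rose (23 adjusted over the list alone, adjusted p = 0.000357 with an estimated correlation). Ly6C+ monocyte genes fell in 10 of 15 (12 down and 1 up adjusted over the list alone, adjusted p = 0.00107 with an estimated correlation) and interferon response genes fell in 9 of 35 (17 adjusted over the list alone, adjusted p = 0.0286 with an estimated correlation). In spleen, Cd300e rose by 5.95 ± 0.39, Fabp4 by 5.76 ± 0.52 and Dnase1l3, a secreted DNase, by 5.68 ± 0.91, Ly6c2 fell by 5.28 ± 0.44, and Cebpb rose by 0.75 ± 0.20 (adjusted p = 0.0369), a call that 7 alternatives ended. In spleen 20 of 24 Ly6C- monocyte genes rose (21 adjusted over the list alone) and 11 of 15 Ly6C+ monocyte genes fell (12 adjusted over the list alone), both at adjusted p = 0.00029 with an estimated correlation. There interferon response genes fell in 4 of 35 (14 adjusted over the list alone, adjusted p = 0.0392 with an estimated correlation). Limma called 443 genes in blood, 204 higher and 239 lower, and 335 in spleen, 192 and 143. Array weights gave 1397 and 1368, a fit of the blood libraries alone 214 and limma without trend 272 in blood. In blood the count was 262 and 184 without Ly6C- replicate A or B and 187 and 269 without Ly6C+ replicate A or B, and in spleen, in the same order, 168, 179, 160 and 207.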

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

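The tests of sex, linked strain sequence, wt reads in the ko libraries, library scaling and mixed gates in the Ly6C- monocyte genes alone were chosen after the results they address were seen, while those of mixed gates, depth and other splits of the samples were planned.

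In ko Ly6Cint monocytes 721 genes differed from wt, 413 higher and 308 lower. Cells of other wt gates in the ko sort are a poor explanation of the whole set, since a mixture cannot leave the range of its parts and both ko libraries lay outside all 6 wt blood libraries for 73.2% of these genes (528 of 721, 320 above and 208 below, where chance gives 21.4% of genes that, like all 721, already lie outside both wt Ly6Cint libraries). For the Ly6C- monocyte genes that fell a share of other gates stays open, because 3 of 12 (25%), Itgal, Apoc2 and Gngt2, lay below all wt blood libraries and 9, Fabp4, Ace and Nr4a1 among them, inside their range. Sex coincides with genotype, and it was checked between host spleen libraries with Xist (B) and those with Y-linked reads (A), 3 each. There 694 called genes not placed on X or Y had a median difference in the ko direction of -0.047 (quartiles -0.304 to 0.204). Their median ko change was 1.55, so the set showed no shift of that size between these host spleen libraries. The 3 libraries of a letter are different sorts that may come from a single animal or pool. They also differ in tissue and age from the ko and wt blood, so sex cannot be set apart from genotype there. Sequence from another strain linked to the targeted allele would raise calls near Cebpb, where 6 of 170 neighbours were called against 678 of 10373 elsewhere, a ratio of 0.54 (Fisher's exact p = 0.154, two-sided, odds ratio 0.189 to 1.17). Variants in a few linked genes need not raise the share over so many neighbours, so the test cannot exclude them. What stays open includes the loss of C/EBPb itself, as a hypothesis, sex, and strain variants of the mixed background, unlinked or in a few linked genes. Such variants may underlie single large changes such as those of Ly6c1, Ifi44, Ifi44l, Rpl26, Emp1, Arsb and Folr2. Cells outside the wt monocyte gates stay open too, since the range test covers those gates only. All 8 called MHC class II and dendritic cell genes and all 6 called tissue macrophage markers lay above all 6 wt blood libraries. The 1 called neutrophil marker lay below them and the 1 called B cell marker inside their range.

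Cebpb was still read in the ko libraries, at 15.3% and 7.64% of the wt mean in Ly6C+ replicates 1 and 2 and at 12.5% and 4.51% in Ly6Cint. Reads or cells of the male wt animals carried into the female ko libraries would bring Y-linked genes at the same share, and 4 such genes stood at 11.3%, 8.43%, 11.9% and 3.83% of wt, ratios to the Cebpb share of 0.739, 1.1, 0.952 and 0.849. Pooled, 82 reads were seen on them where 90.9 were predicted, a ratio of 0.902 (95% interval 0.717 to 1.12), consistent with carry-over, though the pooled form was adopted after a form resting on the lowest library had left the question undecided. Rpl26, chosen after its values were seen, stood at 9.52%, 4.23%, 10.8% and 4.61%. A transcript of the undeleted part of the gene stays open as a further source of Cebpb reads, the route of carry-over was not tested, and ko against wt ratios may be too small to that extent.

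Among blood Ly6Cint against Ly6C+ calls 29.2% were higher, so more genes fell than rose. Lower depth of the Ly6Cint libraries is argued against by thinning the Ly6C+ libraries to 726805 reads, after which 29.7% of calls were higher. With each library scaled to the total of the listed genes 46.9% were higher, which suggests the scaling to a total that includes other reads as a source of the imbalance, while TMM and quantile scaling centre the changes by construction and decide nothing here. A true difference in RNA content per cell stays open, because no value here measures it.

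Other splits of the compared libraries into groups of the same sizes were counted where groups have at least 3 libraries. In 6 comparisons 1 of 35 splits, the real one, called as many genes. That is the smallest share 35 splits allow, and it speaks against chance assignment of the libraries. Chance differences between animals cannot be excluded, because the labels do not say whether replicates are separate animals. The real and highest other counts were 1052 and 1 for cMoP against MDP, 4286 and 1908 for marrow Ly6C+ against cMoP, 2959 and 2751 for blood against marrow Ly6C+, 3092 and 2897 for Ly6Cint against Ly6C+, 2310 and 2094 for blood Ly6C- against Ly6C+, and 4565 and 2885 for marrow Ly6C- against Ly6C+. All but the lowest of these highest others come from a split that exchanges every library but 1, so that it nearly mirrors the real one. For Ly6C- against Ly6Cint blood cells, 1009 and 70, the 10 splits are too few for a share under 0.05. For graft spleen against blood 1 of 100 drawn splits within time points, the real one, called as many genes (458, highest other 339). This speaks against chance assignment with the same limit on animals.

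A library stood far from the others of its group in 4 of 48 sets of values tested, where chance gives about 1 in 20. In cMoP, replicate 1 had Cebpb at 164.3 RPM, with 123.7 to 129.9 in the others, and 3643327 recovered reads, with 2346211 to 2555374, and replicate 2 had 12212 genes above 0, with 12462 to 12512. In marrow Ly6C- cells, replicate 3 had Cebpd at 74.38 RPM, with 105.2 to 111.5 in the others. No explanation was tested.

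The change from Ly6C+ to Ly6C- cells differed between marrow and blood for 2026 genes by limma, 1625 of them with the lower value in marrow, around a median of all genes of -0.28. With quantile scaling 843 were higher and 969 lower around a median of 0.05, and with scaling to the listed genes 547 and 1286 around -0.17. The smallest p belonged to the tubulins Tuba1c (-2.94 relative to the median) and Tuba1b (-3.17). For host spleen against host blood the same test called 0 (271 genes at an unadjusted p under 0.05). The change of grafts from 24 to 48 h differed between spleen and blood for 318 genes, 78 with the higher and 240 with the lower value in spleen around a median of -0.22, and for 67 and 86 with quantile scaling around a median of 0.04. The ko effect differed between Ly6Cint and Ly6C+ cells for 1 gene, Capg.

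The duplicate marrow libraries of the knockout table enter no comparison. S100a8 averaged 472 RPM in their MDP and 466 in their cMoP, against 10.7 and 16.5 in the 7-week table, but in their Ly6C+ cells it was lower, at 70 against 149. Hbb-b1 averaged 245, 253 and 2870 in their MDP, cMoP and Ly6C+ cells, against 39, 16.1 and 59.4. The tables were made separately, and this difference was not tested.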

How the results depend on the processing

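Scaling to the total of the listed genes, edgeR on recovered reads, array weights, leaving out X and Y genes, other scalings of differences between tissues, the pairwise filter at 20 RPM and a block on time and letter across graft tissues were chosen after seeing the data, and the other alternatives were planned. Of 443 calls followed, of genes named or qualifying to be named in a comparison, 233 stayed called in every alternative run, 210 lost the call in at least 1, and 0 reversed. Counts of calls that moved by more than 1.5 times follow. Where leaving out a library leaves 1 in a group, the lone sample is assumed to vary like the other groups. EdgeR was not run in the transfer table, whose depth is unknown. Libraries that share a replicate number did not deviate together beyond 0.1 in every pair of any set: after removing group means their mean r was -0.00399 in the 7-week table (0.00159 for other numbers), 0.104 in wt blood (2 of 6 pairs over 0.1), 0.0368 in host blood and 0.0587 in host spleen. In host spleen letter A goes with Y-linked reads and B with Xist in all 3 populations, so letters there follow sex, and in host blood they do not. The planned replicate block gave 185 calls for graft spleen at 48 against 24 h and stayed within 1.5 times for the other counts, 293 in host spleen among them. For graft spleen against blood, a replicate block on time and letter (B with B, AC with C) gave 954 calls, 458 of them shared, though such libraries did not deviate together (r = 0.00741, -0.0221 and 0.00501 after 24, 36 and 48 h). No paired analysis was possible because graft and pretransfer, and graft and host libraries, share only the letter B. Depth limits what the 7-week table can show, with 577690 reads in its smallest library. Simulation for the blood grafts, at an assumed spread and depth, recovered none of the 2-fold changes.

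With only the compared groups in the fit, which leaves fewer libraries to estimate the spread, the counts were 2616 for cMoP against MDP, 1415 for blood against marrow Ly6C+, 675 for Ly6Cint against Ly6C+, 1 for Ly6C- against Ly6Cint, 719 for blood Ly6C- against Ly6C+, 739 in wt blood, and 0 for ko Ly6C+, ko Ly6Cint and their difference by limma (1091, 2094 and 677 genes at an unadjusted p under 0.05 in the whole table). In the transfer table they were 7 for graft blood at 48 against 24 h (0 shared with the 979), 0 for spleen at 48 against 24 h (1957 at an unadjusted p under 0.05 in the whole table), 57 for spleen against blood (32 shared), 492, 0 and 281 for grafts against host Ly6C+ (173 shared), Ly6Cint and Ly6C- cells (20 shared), and 214 for host blood (78 shared).

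Array weights gave 3252 for cMoP against MDP, 1562 for Ly6Cint against Ly6C+, 351 for ko Ly6C+, 2149 for wt, 996 for grafts at 24 h against pretransfer, 9 and 12 at 48 against 24 h in blood and spleen, 26 for spleen against blood, 514, 74 and 92 against host Ly6C+, Ly6Cint and Ly6C- cells, and 1397 and 1368 for the hosts in blood and spleen, and the cause was not tested. Quantile normalization gave 601 for Ly6C- against Ly6Cint, 187 for graft spleen at 48 against 24 h, 222 for spleen against blood, and 199 and 265 against host Ly6Cint and Ly6C- cells. EdgeR called 1981 for Ly6Cint against Ly6C+, 415 for Ly6C- against Ly6Cint and 8 for the difference between the ko effects, for which no filter gave 4, a pseudocount of 5 gave 6 and limma without trend 0. Limma without trend gave 272 in host blood. Quantile scaling left 153 of the differences between graft spleen and blood, 130 of them among the 318. Without X and Y genes the ko counts were 130 in Ly6C+ and 707 in Ly6Cint cells. For none of these was the cause tested.

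Leaving out each library in turn gave 856 to 923 calls for cMoP against MDP, 3436 to 3831 for marrow Ly6C+ against cMoP, 2186 to 3358 for blood against marrow, 2198 to 3603 for Ly6Cint against Ly6C+, 251 to 1937 for Ly6C- against Ly6Cint, 1824 to 2733 for blood Ly6C- against Ly6C+ and 3811 to 4406 in marrow. It gave 34 to 73 for ko Ly6C+, 224 to 658 for ko Ly6Cint, 0 to 3 for their difference and 616 to 732 in wt. For grafts it gave 639 to 1728 at 24 h against pretransfer, 891 to 1672 and 73 to 688 at 48 against 24 h in blood and spleen, 217 to 1043 for spleen against blood, and 346 to 1719, 54 to 1138 and 25 to 1209 against host Ly6C+, Ly6Cint and Ly6C- cells, and for the hosts 184 to 269 in blood and 160 to 207 in spleen. The correlation of position with time was 0.881 to 0.959 in blood and 0.963 to 0.989 in spleen, and with 1 of the 36 h libraries left out the design allows no exact p under 0.05.

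The signature of 50 genes put wt Ly6Cint at 71.46, pretransfer cells at -34.74, blood grafts at 36 h at 59.68 and spleen grafts at 51.07, 66.44 and 111.9 by time. A pseudocount of 5 put pretransfer cells at -31.91, blood grafts at 36 h at 62.33 and spleen grafts at 48 h at 99.25. The signature from another set of animals put ko Ly6C+ at -14.56, ko Ly6Cint at 16.58, wt Ly6Cint at 66.38, pretransfer cells at -24.41, blood grafts at 36 h at 59.32 and spleen grafts at 58.06 after 24 h and 108.1 after 48 h. Over the 5305 genes of at least 20 RPM in every table r of the Ly6C- minus Ly6C+ change was 0.824 (7-week and wt), 0.79 (7-week and host) and 0.887 (wt and host), and over genes of at least 20 RPM in both tables compared 0.82, 0.77 and 0.882. With an estimated correlation 84 list tests were called in place of 170. The cause was not tested.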

Other observations

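The class II and granulocyte genes given here were chosen after their values were seen, while the gene lists were fixed beforehand. For the MHC class II genes, which present peptides to T cells, a rise from Ly6C+ to Ly6C- cells was called in some tissues and tables only. The Ly6C- minus Ly6C+ log2 ratio was 3.77 for H2-Ab1 and 4.77 for H2-Eb1 in 7-week blood and 4.89 and 5.86 in marrow. In wt blood of the knockout table these were 0.17 and 1.14 (adjusted p = 0.936 and 0.45 by limma), and in host blood -0.66 and -0.13 (adjusted p = 0.854 and 1). Host spleen gave 2.47 and 3.62, though the direct test of host spleen minus host blood called 0 genes by limma (271 at an unadjusted p under 0.05). H2-DMa, which loads peptides, was at -0.51 in 7-week blood (adjusted p = 0.0748), and fell by 1.32 in wt blood and by 2.12 in host blood. The tables hold animals of different age and background, and differences between them were not tested.

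The MDP and cMoP duplicates of the knockout table had higher values of S100a9 and Elane than the 7-week sorts of the same name. S100a9 averaged 1210 RPM in MDP and 1110 in cMoP, where the 7-week means were 39.6 and 11.3. Elane, the elastase of primary granules, averaged 384 and 2870 against 67.3 and 1290, and Kit, the receptor of progenitors, 94.4 against 77.8 in MDP and 35.6 against 71.9 in cMoP. In Ly6C+ cells S100a9 averaged 147 against 132, Elane 262 against 159 and S100a8, lower there, 70 against 149. Cebpb stood at 42.13 and 53.55 in the MDP duplicates, at 147.1 and 153.6 in cMoP and at 520.9 and 435.5 in Ly6C+ cells, the order of the 7-week table.

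The neutrophil marker list was called in grafts between 24 and 48 h in blood, where 2 of 12 genes fell, Camp and Ltf (2 adjusted over the list alone), a call lost at adjusted p = 0.14 with an estimated correlation. From marrow to blood Ly6C+ cells 1 of its 12 genes rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.894). After 24 h in blood 1 of 12 rose, Ltf (1 adjusted over the list alone), with adjusted p = 0.329 with an estimated correlation. The platelet marker list was called in none of the 20 comparisons. Of its genes Itga2b and Pf4 were higher in marrow Ly6C- than Ly6C+ cells, 2 of 3 measured (2 adjusted over the list alone, camera adjusted p = 0.0897).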
